A study of Mus musculus with 2 samples.

How the data were processed

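Gene expression was measured by sequencing of poly-A RNA in MS1 cells, an immortalised endothelial line from mouse pancreatic islets. Per the labels, the cells carried a lentiviral short hairpin RNA against LacZ, a bacterial gene absent from the mouse genome, or against Pspc1. There was 1 library per group, so 2 libraries in all, and the groups were taken from the treatment label. Per the labels' protocols, total RNA was extracted with TRIzol, poly-A RNA was enriched with oligo-dT beads, and libraries were made with the NEBNext Ultra RNA kit. The labels do not state a strand-marking kit, so reads of a gene and of an overlapping antisense gene were treated as not separable. The hairpin sequences were not given in the sources used here.

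Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.0 and DESeq 1.39.0, with the mouse genome build mm10. The notes used here list these names without a role or an order. The gene annotation, the treatment of reads that map to several places, the filter on low genes and the scaling formula were not given in the sources used here. The deposited values are a gene-level signal on a continuous scale, made by the authors, and each table lists the same 11405 genes by Ensembl identifier. The values sum to 980876 in the control library and to 1054228 in the knockdown library, so they are neither raw counts nor CPM of the listed genes. Every deposited value was a whole multiple of a single step per library, within a tolerance of 0.01 reads (100% of values in both libraries). That step, the worth of 1 read, was 0.0153 in the control library and 0.0197 in the knockdown library. Dividing by the step gave 64009912 reads on the listed genes in the control library and 53518762 in the knockdown library. No gene was listed at 0, and the lowest mean of both values was 0.37. Genes that are not listed were not analysed here.

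The design fixed before the data were examined had assumed raw counts, with median-of-ratios scaling. Because the deposited values had already been scaled by the authors, they were used as deposited, as the design provides for that case, and median-of-ratios scaling became an alternative. The thresholds written for scaled counts were applied to the deposited values. For each gene the log2 ratio of knockdown over control was taken as log2((knockdown + 0.5)/(control + 0.5)). This pseudocount understates the change of genes with low values. Genes with a mean of both values of at least 50 and a change of at least 2-fold met the size rule and are called higher or lower. Without replicates no spread between cultures can be measured, so no p-value was computed and no difference has a replicate check. For single genes, a 95% exact counting interval of the ratio without pseudocount (conditional binomial, Clopper-Pearson) was computed from the whole reads behind the deposited values. These reads carry no molecular identifiers, and the intervals cover counting error only. They compare 2 libraries, not 2 conditions. Among genes with a mean of at least 50, the fewest reads in a library were 1290, the median interval was 0.10 log2 wide and the widest 0.18.

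In all, 41 gene lists and 9 sets of cell type markers were fixed before the data were examined. A list entered with its members of mean value of at least 20. Its median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5, which describes these 2 libraries and is not a test across samples. Lists with fewer than 5 such members (3 of 41) were given values only.

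The genes named in the text followed a rule fixed in advance. It names Pspc1, then the 12 genes with the largest change in each direction among those that met the size rule with a mean of at least 100 and do not have a predicted or clone name. It adds up to 4 members per described list with the largest absolute log2 ratio among members of mean 50 or more, then Nono, Sfpq and Neat1. Last come the markers that met the size rule and 6 commonly used reference genes. A gene that the rule would name is not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

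Gene symbols were found for 11399 of the 11405 identifiers, and the other 6 are not named. Coordinates, exonic length (all exons of a gene merged) and exon overlaps came from GENCODE release M21, on the same genome build. That annotation gave a length for all 11405 genes and a GC content for 11399. Whether the authors counted with this release is not known. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

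The steps were tested on simulated reads for the same 11405 genes, with 200 genes changed. The simulation held counting error only, with no spread between cultures and with genes that varied independently. It checks the calculation and gives no rate of false calls or of missed changes between 2 cultures, for genes or for lists. All simulated 3-fold higher genes were recovered (100%). Of the 3-fold lower genes, 24% fell under the mean of 50 and could not meet the rule, and 100% of the others were recovered. No gene changed by 1.5-fold (0%) and no unchanged gene (0) met the rule. The counting intervals held the true ratio for 95.4% of genes. Of 200 unshifted random lists 6% stood apart, and a list shifted by 0.3 log2 reached percentile 100.

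The alternatives fixed in advance covered scaling by a trimmed mean of M values and by total reads, a pseudocount of 5, thinning of the control library, other minimum means, a fold of 1.5, an interval beyond 1.5-fold and several ways of matching the random lists. The trimmed mean was computed from its formula, trimming 30% of ratios and 5% of means. Median-of-ratios scaling, no pseudocount, the rules applied to reads instead of deposited values, and matching or correction for GC content were added after the data had been seen.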

Results

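The transcriptome of MS1 cells was compared between a library from cells with a LacZ hairpin and a library from cells with a Pspc1 hairpin. Pspc1 encodes paraspeckle component 1, an RNA-binding protein of the DBHS family that is found in paraspeckles, nuclear bodies built on the long noncoding RNA Neat1. The series states its aim as a comparison of the RNA profiles of both lines by gene sets. Each group held 1 library, with 64009912 reads on the listed genes in the control library and 53518762 in the knockdown library. The 10 most abundant genes took 6.29% of the reads in the control library and 7.12% in the knockdown library. Values are given as deposited, control first, and no value has a replicate error.

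The targeted gene was lower in the library labelled as its knockdown. Pspc1 (ENSMUSG00000021938, mm10 chromosome 14, 56720710 to 56778316, minus strand) had a value of 28.8 in the control library and 3.78 in the knockdown library, or 7.62-fold less. The log2 ratio was -2.77 with the pseudocount, and the 95% counting interval of the ratio without it ran from -3.15 to -2.71 on the log2 scale. These values rested on 1880 and 192 reads over 5734 bp of exons. The mean of both values lay under the minimum of 50, so Pspc1 was not counted in the size rule. With a pseudocount of 5 its log2 ratio was -1.94. Among reference genes, Gapdh had values of 5865 and 6323, Actb 5761 and 7466, Ppia 2048 and 2106, and Pgk1 1307 and 1626. Hprt had 74.4 and 64.6, and Tbp 20.3 and 15.1. Their log2 ratios lay between -0.41 for Tbp and 0.37 for Actb, and that of Ppia turned from 0.04 to -0.06 when scaled by total reads.

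Most well-measured genes differed little between the libraries. Of 3629 genes with a mean value of at least 50, 89.5% lay within 0.5 log2 of equality, 20 were at least 2-fold higher in the knockdown library and 34 at least 2-fold lower. The genes lower by the largest factor included an endoplasmic reticulum disulfide isomerase (Pdia3), an angiogenic growth factor (Angpt2) and a cytoskeletal linker (Plec). Those higher by the largest factor included keratin 19 (Krt19), a matrix proteoglycan (Bgn) and a small heat shock protein (Cryab). The share of higher genes among those called was 37.0%, and it depended on the scaling. Counts were 23 higher and 25 lower with a trimmed mean of M values (47.9% higher), 23 and 24 with median-of-ratios scaling (48.9%), and 17 and 47 when scaled by total reads (26.6%). Scaling by total reads moved the median log2 ratio of all genes by -0.10, while 17 higher and 24 lower genes were called under every scaling.

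**Figure D1:**
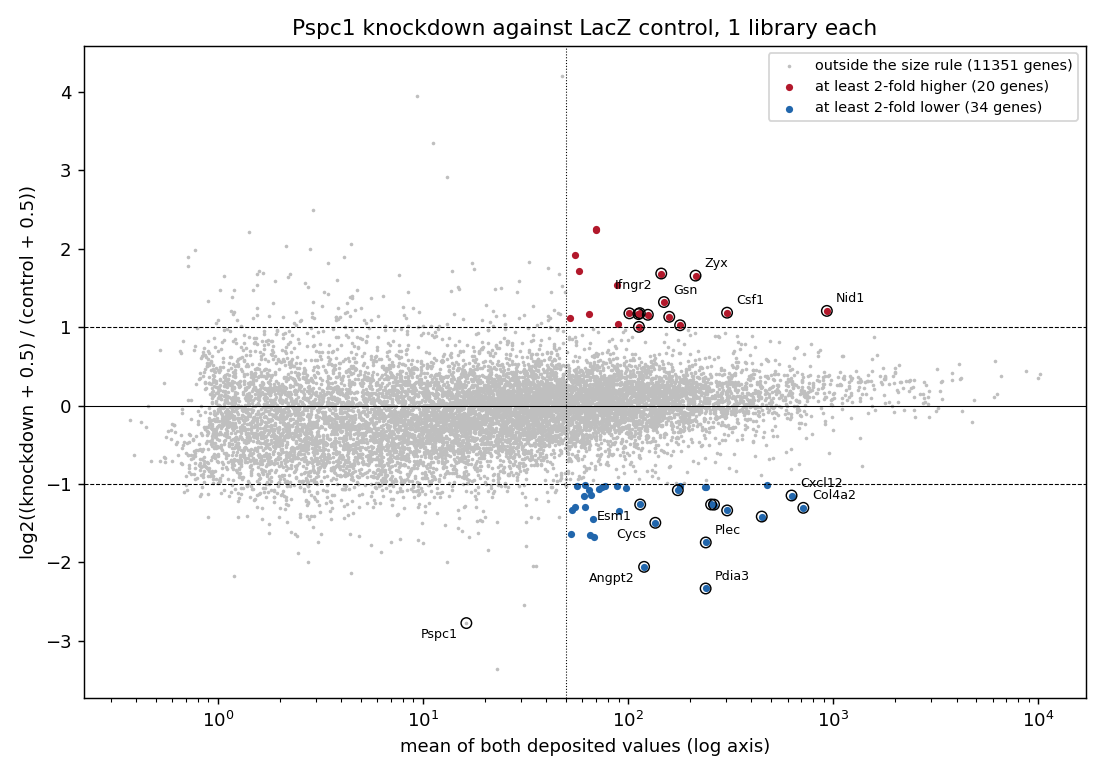
Log2 ratio of knockdown over control against the mean of both deposited values (log axis), with 1 point per gene. Red and blue points are the 20 higher and 34 lower genes of the size rule, the dotted line is the minimum mean of 50, dashed lines mark 2-fold, and circles mark Pspc1 and the 24 genes named by fold, some of them with their symbols.

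The 12 genes of mean 100 or more named by fold as lower in the knockdown library had varied functions. Pdia3 (ENSMUSG00000027248, mm10 chromosome 2, 121413775 to 121438687, plus strand) fell from 399.6 to 78.9, 5.07-fold, with a counting interval of -2.39 to -2.29 log2. Canx, the membrane chaperone calnexin with which Pdia3 works on glycoproteins, went from 237.9 to 112.3 (2.12-fold lower, but a log2 ratio of -0.75 after a correction for length and GC). Angpt2 (ENSMUSG00000031465, mm10 chromosome 8, 18690263 to 18741562, minus strand), the Tie2 ligand angiopoietin 2, went from 193.6 to 46.1 (4.20-fold lower, interval -2.13 to -2.01). Esm1, a proteoglycan of endothelial tip cells, went from 162.1 to 67.3, the chemokine Cxcl12 from 865.1 to 390.2, and the semaphorin receptor Plxnd1 from 371.3 to 154.3. Col4a2, a basement membrane collagen chain, had 1020 in the control library and 412.5 in the knockdown library. Plec, which encodes plectin, went from 369.5 to 109.8, and Tpm4, a tropomyosin, from 359.2 to 149.5. Metabolic genes in the group were Fasn, the fatty acid synthase (653.8 to 244.6, 2.67-fold lower), and Cycs, cytochrome c (201.0 to 71.0, 2.83-fold lower). The ubiquitin ligase gene Rnf10 went from 436.7 to 172.5. Reads of Cycs can be shared with its processed pseudogenes, and exons of Plec overlap Parp10 (mean value 56.4) and those of Col4a2 overlap Col4a1, so these values carry that uncertainty.

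The 12 genes of mean 100 or more named by fold as higher in the knockdown library had varied functions. Ifngr2 (ENSMUSG00000022965, mm10 chromosome 16, 91547072 to 91565623, plus strand) rose from 68.7 to 221.9, 3.23-fold, with a counting interval of 1.64 to 1.74 log2. Zyx (ENSMUSG00000029860, mm10 chromosome 6, 42349630 to 42360213, plus strand), which encodes zyxin, rose from 102.6 to 324.6 (3.16-fold, interval 1.62 to 1.70). Gsn, the actin-severing protein gelsolin, went from 85.5 to 214.2, and Nid1, a linker of basement membrane proteins, from 563.8 to 1302. The macrophage growth factor gene Csf1 went from 185.8 to 422.8 and Selp, the leukocyte adhesion receptor P-selectin, from 69.8 to 158.7. Nfkbia, an inhibitor of NF-kB that NF-kB itself induces, went from 75.1 to 151.2 and lay at the edge of the rule (2.01-fold). After a correction for length and GC the log2 ratios of Nfkbia (0.86), Efhd2 (0.92) and Snhg8 (0.99) no longer reached 2-fold. Nor did Nfkbia (0.90) and Mvp (0.92) when scaled by total reads, or with a pseudocount of 5. The remaining named genes were Snhg8, a small nucleolar RNA host gene (62.2 to 141.1), Neurl3 (69.1 to 155.8), the myosin chaperone gene Unc45a (77.2 to 172.9), Efhd2 (99.4 to 218.5) and Mvp, the major vault protein (118.2 to 240.9).

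**Figure D2:**
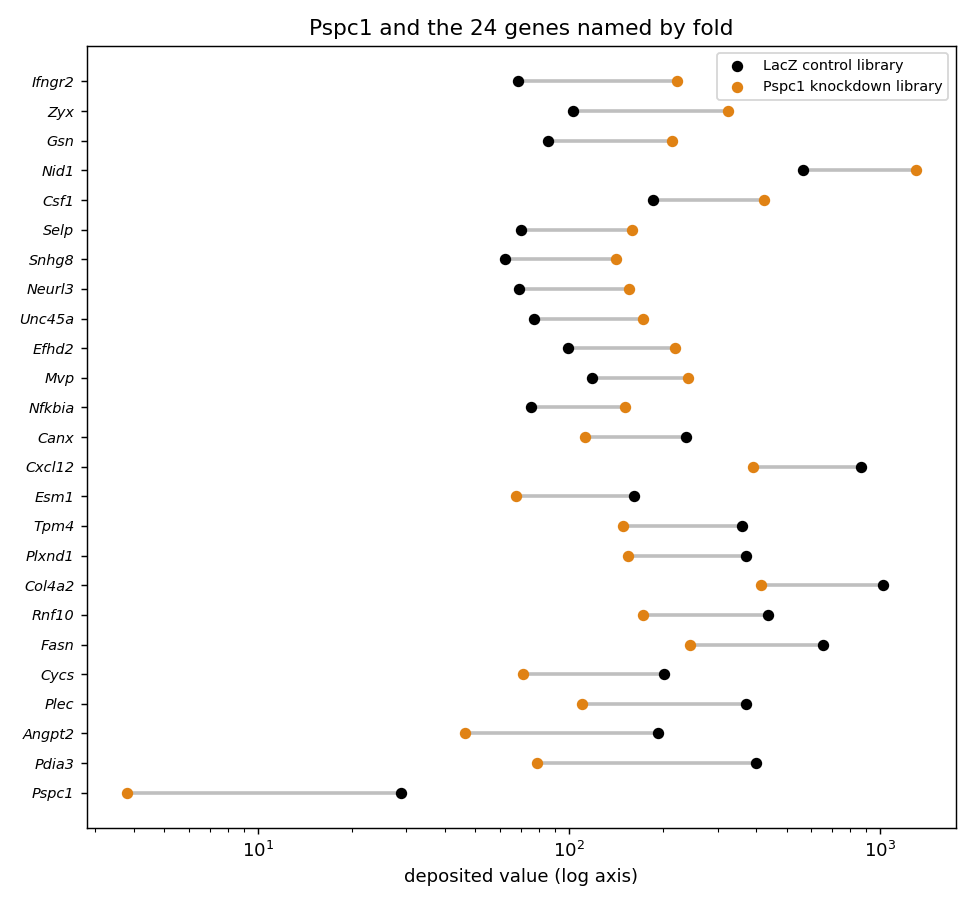
Deposited values (log axis) of Pspc1 and of the 24 genes named by fold in the LacZ control library (black) and the Pspc1 knockdown library (orange), joined by a grey line per gene. Pspc1 goes from 28.8 to 3.78, Pdia3 from 399.6 to 78.9 and Ifngr2 from 68.7 to 221.9.

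The log2 ratio also followed gene length and base composition. Across the 5892 genes with a mean of at least 20, Spearman's rho of the log2 ratio was -0.32 with exonic length and 0.28 with GC content. Genes are not independent replicates, and the 2 properties were related to each other (rho -0.23). The median log2 ratio was 0.18 in the 10% of genes with the shortest exons and -0.20 in the 10% with the longest. The 34 lower genes had a median exonic length of 5188.5 bp and the 20 higher genes of 4033 bp, against 3973 bp for all genes with a mean of at least 50. The median exonic length of each list that stood apart below is therefore given beside its values.

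**Figure D3:**
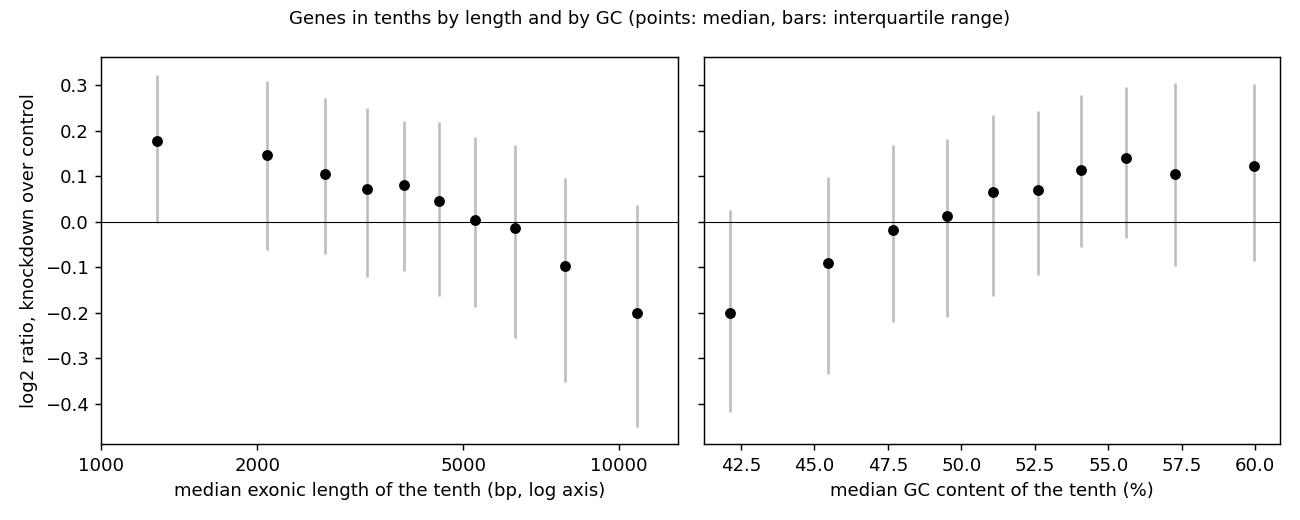
Median log2 ratio of knockdown over control in 10 groups of nearly equal size made from the 5892 genes with a mean value of at least 20, ordered by exonic length in bp (left, log axis) and by GC content in percent (right). Bars span the interquartile range of each group, and the medians run from 0.18 for the shortest genes to -0.20 for the longest.

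Of 38 gene lists with enough members, 17 stood apart from random lists of like expression, 7 of them high and 10 low, where 5% would be 1.9 lists. The lists share some genes and are not independent. Members of a list can also vary together between any 2 cultures. The 5% holds only for lists of unrelated genes, so the excess over it is not evidence of an effect of the knockdown.

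Inflammatory genes stood higher as a group. Of 14 measured NF-kB inflammatory genes, 3 met the size rule as higher (Csf1, Selp and Nfkbia, the last not under the 3 alternatives named above), none as lower, and 11 had a log2 ratio above 0. The median was 0.85, at percentile 100 of random lists, whose central 95% ran from -0.13 to 0.22. Ier3, an early response gene that did not meet the rule, had values of 146.9 and 280.0. The 12 measured genes of MHC class I antigen presentation all had a log2 ratio above 0, with a median of 0.52 (percentile 100), but none met the size rule. The class I heavy chains H2-D1 (664.2 and 1028), H2-K1 (249.3 and 405.3) and H2-Q4 (40.3 and 71.4) share sequence, so reads may have been split among them. Psmb8, an immunoproteasome subunit, had 40.3 and 70.7. Of the 7 measured interferon-stimulated genes only 3 had a mean of at least 50, and none met the rule. The list median of 0.21 lay at percentile 93.9, or 99.87 with members down to a mean of 5 and 98.0 with members down to 20 reads. Median exonic lengths were 4386.5 bp for the NF-kB list, 2767 bp for MHC class I and 1885 bp for the interferon list.

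The Notch and angiogenesis lists stood lower. Of 9 measured Notch pathway genes, 3 met the size rule as lower, with a list median of -0.39 (percentile 0.15). These were the receptors Notch4 (80.3 to 25.4, 3.16-fold) and Notch1 (99.5 to 36.1) and the ligand Dll4 (78.9 to 31.9). Nrarp, a Notch target, did not meet the rule, with values of 70.4 and 96.4. Of 19 angiogenesis and tip cell genes 5 met the rule as lower and none as higher. They were Angpt2, Dll4, Esm1, Cxcl12 and the placental growth factor gene Pgf (101.0 to 48.9), of which Pgf was named after its values were seen. Pgf fell short of 2-fold with a trimmed mean of M values or median-of-ratios scaling (log2 ratios of -0.998 and -0.99) and with a pseudocount of 5 (-0.98), which leaves 4 of the 5. Members of the angiogenesis list went both ways, with 8 log2 ratios above 0 and 11 below. The list median was -0.12 (percentile 0.24, and 3.16 with random lists not matched on expression). Median exonic lengths were 5528 and 4161 bp. The 32 endothelial identity genes stayed inside the range of random lists (median 0.002, percentile 2.61), and none met the rule. Among them Kdr, the main VEGF receptor, had 148.9 and 77.3, Cdh5, VE-cadherin, 859.4 and 511.2, Cav1 796.4 and 455.9, and Sox18 82.5 and 47.3. Their mean log2 ratio of -0.10 lay at percentile 0.09, members of mean 100 or more lay at percentile 1.94, and the median turned to -0.10 with scaling by total reads.

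Extracellular matrix genes had the lowest list median, although members went both ways. Of 20 measured genes Col4a2 and Fn1 were lower (Fn1, fibronectin, 639.3 to 317.1, which fell short of 2-fold under 3 alternatives), and Nid1 and Bgn were higher (Bgn, the proteoglycan biglycan, 23.9 to 115.2, 4.81-fold). The median was -0.49, at percentile 0, and 13 members had a log2 ratio below 0. The log2 ratio of Fn1 was -0.97 with a trimmed mean of M values, -0.96 with median-of-ratios scaling and -0.79 after the length and GC correction. Their median exonic length was 7203.5 bp. Of 8 integrin genes 1 met the rule as lower, Itga6 (87.9 to 41.3, but a log2 ratio of -0.88 after the length and GC correction). The integrin list had a median of -0.36 (percentile 0.11, 6458 bp), and 3 of the 8 genes had a log2 ratio above 0. Itgb4, named after its values were seen, had 53.6 and 8.75, but its mean of 31.2 was too low for the rule. Itgb3 (194.3 and 299.8), Itga5 (570.3 and 764.6) and Itgb1 (196.6 and 127.1) did not meet the rule. With members down to a mean of 20 reads the integrin list lay at percentile 11.6. The 20 endothelial junction genes had a median of -0.22 (percentile 0.06, 6326.5 bp), yet the only member that met the rule was higher, the claudin gene Cldn12 (45.2 to 132.1). Their mean log2 ratio of -0.10 lay at percentile 3.23. Cdh5, Vcl (88.3 and 50.3) and Jup, plakoglobin (66.2 and 119.1), did not meet the rule. Matrix proteases and inhibitors stood high (15 genes, median 0.27, percentile 98.4, 5302 bp) with none meeting the rule. Plat had 107.1 and 152.4, Plau 1550 and 1162, and Adamts4 74.96 and 40.0. That list's mean of 0.10 lay at percentile 72.4, and its members of mean 100 or more at percentile 97.3.

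Genes of RNA processing stood lower by small amounts. None of 24 measured paraspeckle genes met the size rule, while 20 had a log2 ratio below 0, with a median of -0.24 (percentile 0.02). Neat1 (ENSMUSG00000092274, mm10 chromosome 19, 5824708 to 5845478, minus strand) had 128.6 and 77.8, with a counting interval of -0.78 to -0.67 log2. The partner proteins of PSPC1 in the DBHS family differed less, with 417.4 and 457.5 for Nono and 133.6 and 107.8 for Sfpq. Among the other members of mean 50 or more, Hnrnph1 (78.9 and 43.7), Tardbp (97.4 and 61.9) and Hnrnpk (413.3 and 307.8) differed most. Of 32 splicing factors of the SR and hnRNP families, 29 had a log2 ratio below 0, and 1 met the rule, Hnrnpa2b1 (319.3 to 155.5, 2.05-fold lower), which has pseudogene copies. Hnrnpa2b1 fell short of 2-fold with a trimmed mean of M values or median-of-ratios scaling (log2 ratio -0.99 with both) and after the length and GC correction (-0.68). Hnrnpu had 116.8 and 61.9 and Hnrnpm 137.2 and 88.7. The median was -0.29 (percentile 0). These lists share 4 measured genes and had median exonic lengths of 5596 and 6209.5 bp.

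Ribosomal and lysosomal genes stood slightly higher. Of 74 genes of cytosolic ribosomal proteins, 73 had a log2 ratio above 0, none met the size rule, and the median was 0.31, at percentile 100. Random lists of like expression were themselves above 0, centred on 0.19 with a central 95% of 0.14 to 0.26. Rps12 had 1242 and 1868, Rpsa 4936 and 7343, Rplp1 3380 and 4873, and Rpl39 520.5 and 712.4. These genes have many pseudogene copies and were short (median 1805.5 bp). Autophagy and lysosome genes had a median of 0.27 (36 genes, percentile 99.99, 4541.5 bp) with 30 members above 0 and none meeting the rule. The lysosomal hydrolase genes Neu1 (108.8 and 190.7), Ctsd (420.5 and 627.0) and Hexa (270.9 and 398.9) and the cholesterol carrier gene Npc2 (210.2 and 298.1) were among the higher members. Outside that list, the lysosomal enzyme genes Ctsh (118.3 to 58.1) and Hgsnat (241.6 to 118.4) met the rule as lower. They were named after their values were seen. Both fell short of the rule with a trimmed mean of M values, median-of-ratios scaling or the larger pseudocount. Nuclear genes of oxidative phosphorylation had a median of 0.17 (70 genes, percentile 98.9), and the only member that met the rule was lower, Cycs. Ndufv2 had 134.1 and 78.6, Uqcr10 185.7 and 261.7, and Ndufa8 187.5 and 257.2. With a median length of 1696.5 bp, that list fell to percentile 55.9 when random lists were matched on length as well. It also lay inside the range as a mean (percentile 96.9), with members of mean 100 or more (94.7) and with matching on length and GC together (86.0).

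G1/S, actin cytoskeleton, TGF-beta target and clock genes also stood apart. G1/S genes had a median of -0.11 (36 genes, percentile 0.29, 4347 bp), and none met the size rule. Mcm7, a subunit of the replicative helicase whose exons overlap the more abundant Cops6, had 581.1 and 313.4, and Pole 72.2 and 49.8. Members of mean 100 or more lay at percentile 3.03. Actin cytoskeleton and SRF target genes had a median of -0.05 (23 genes, percentile 0.39, 4743 bp), with Zyx higher and Tpm4 lower. The sign of that median turned to 0.004 with median-of-ratios scaling, and the list lay at percentile 3.51 with length matching, 5.64 with length and GC matching and 15.5 without matching. TGF-beta target genes stood at percentile 2.42 (17 genes, median -0.09, 4179 bp) and inside the range under 8 of 12 alternatives, at percentiles up to 14.8. Col4a2 and Fn1 were their only members that met the rule, both lower (Fn1 at the edge), while Col4a1 (1736 and 1017) did not. All 7 measured circadian clock genes had a log2 ratio above 0 (median 0.40, percentile 99.9, 6320 bp). Only 3 of them had a mean of at least 50, and none met the rule. These 3 were Csnk1d (391.7 and 438.4, log2 ratio 0.16), Csnk1e (110.9 and 119.7, 0.11) and Tef (73.5 and 121.7, 0.72). The clock list lay at percentile 96.1 with members down to a mean of 5 and at 95.2 with members down to 20 reads.

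**Figure D4:**
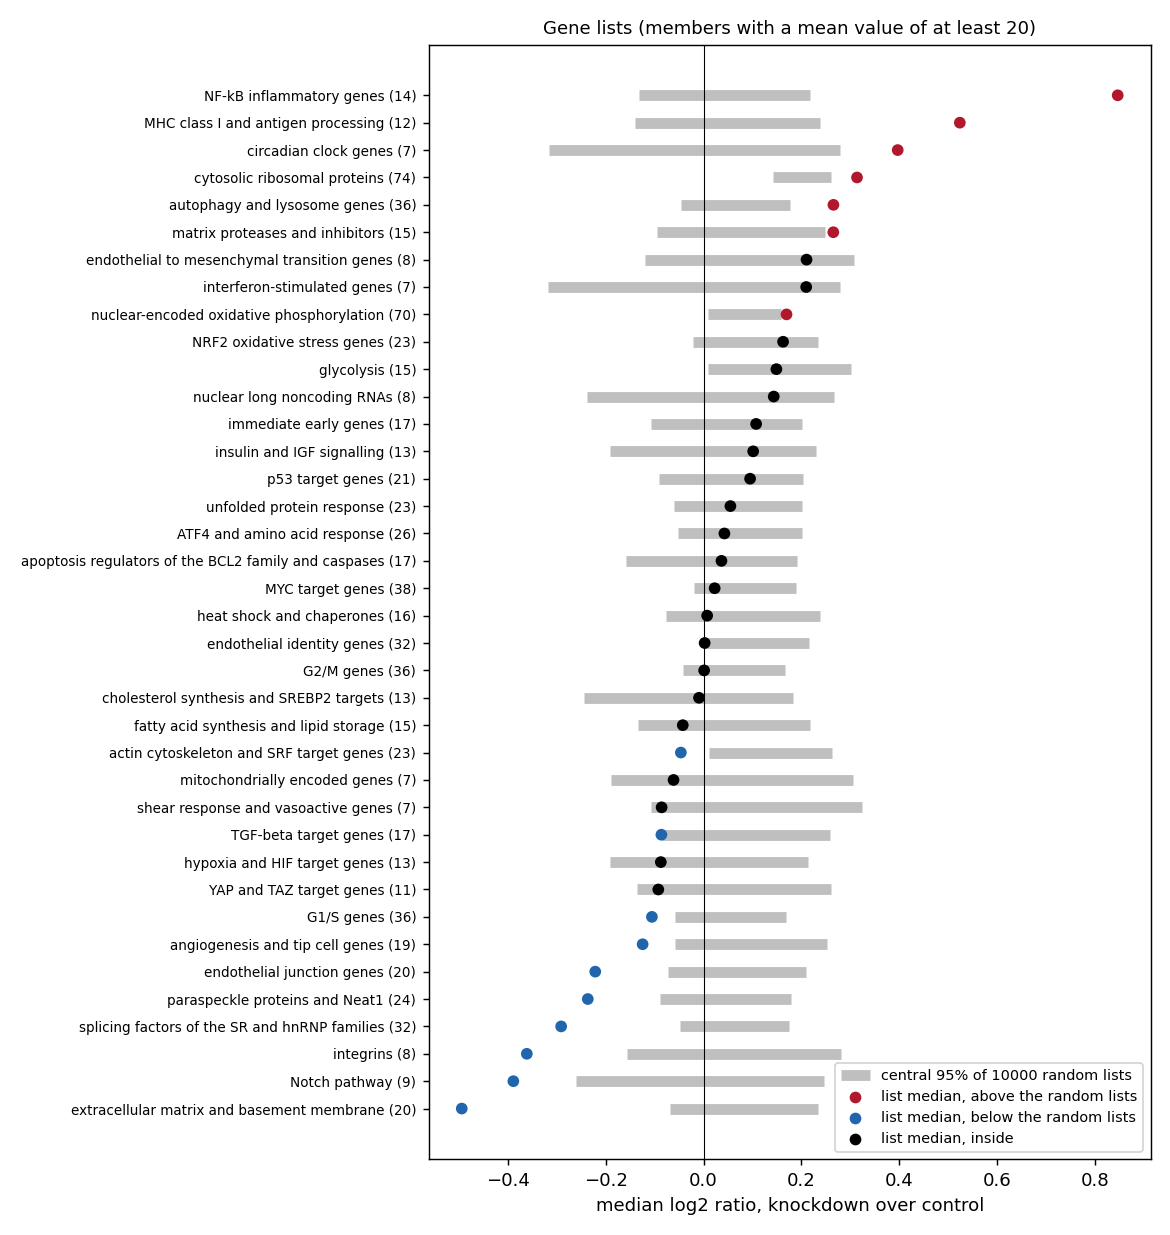
Median log2 ratio of knockdown over control (horizontal axis) of 38 gene lists, with the number of members of mean value of at least 20 in brackets. Grey bars are the central 95% of 10000 random lists matched on mean expression, and red and blue points are the 7 lists above and the 10 lists below that range, from NF-kB inflammatory genes at 0.85 to extracellular matrix genes at -0.49.

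The remaining lists lay inside the range of random lists. In the unfolded protein response list (23 genes) Pdia3 and Canx were lower, the median was 0.05 (percentile 35.8; -0.05 when scaled by total reads) and the mean -0.13, with Hspa5 at 324.0 and 231.8 and Xbp1 at 107.3 and 160.8. As a mean, that list lay at percentile 0.86. The heat shock list (16 genes, percentile 18.0) held 1 higher gene, the small heat shock protein Cryab (22.7 to 87.1, 3.84-fold), and Hspb1 had 281.6 and 520.9. In the fatty acid synthesis and lipid storage list (15 genes, percentile 15.6) only Fasn met the rule. In the list of endothelial to mesenchymal transition genes (8 genes, median 0.21, percentile 82.4) only Fn1 met it, at the edge. No member met the rule among G2/M genes (36 genes, percentile 12.7), MYC target genes (38, percentile 11.3), p53 target genes (21, percentile 67.7) or BCL2 family and caspase genes (17, percentile 52.9). Cenpa had 125.6 and 224.8, Npm1 171.1 and 109.2, Cdkn1a, which encodes the cell cycle inhibitor p21, 500.5 and 838.6, and Bak1 237.7 and 440.8. The same held for glycolysis (percentile 46.0), cholesterol synthesis (51.8), hypoxia (14.9), the ATF4 response (29.6), NRF2 targets (81.3), immediate early genes (75.7), insulin and IGF signalling (74.4), YAP and TAZ targets (5.22) and shear response genes (4.43). Hmox1, heme oxygenase, had 432.2 and 241.4, Nqo1 48.3 and 81.0, Dusp5 125.7 and 206.6, and Akt1 1161 and 760.9. Mitochondrially encoded genes (percentile 14.005) took 0.40% of the reads in the control library and 0.35% in the knockdown library. Nuclear long noncoding RNAs (8 measured, percentile 82.8) had a median of 0.14 and a mean of -0.03, with Snhg8 higher. Among them, MYC targets taken as a mean (percentile 0.36), YAP and TAZ targets of mean 100 or more (1.79), shear response genes with length matching (1.78), long noncoding RNAs with GC matching (98.4), or with length and GC matching, and G2/M genes with members down to 20 reads (0.01) stood apart. BMP target genes (4 measured), Wnt target genes (4) and replication-dependent histones (1) were too few for a percentile. With members down to 20 reads the 11 histone genes had a median of 0.22 and stood high (percentile 98.7), while BMP and Wnt targets lay at 89.5 and 21.97. Poly-A selection measures only the polyadenylated part of histone transcripts, so this does not give their level. Of the members with a mean of 50 or more, Gata2 had 72.9 and 103.1 and Cd44 309.1 and 260.1.

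Markers of other cell types were mostly not listed. None of 10 markers was listed for smooth muscle and pericytes or for islet endocrine cells, and 3 of 10 for fibroblasts, 2 of 12 for leukocytes, 1 of 10 for epithelium, 1 of 10 for pancreatic acinar and duct cells and 4 of 7 for lymphatic endothelium. The listed acinar and duct marker was Krt19 (ENSMUSG00000020911, mm10 chromosome 11, 100140810 to 100148665, minus strand), a keratin of simple epithelia. It rose from 23.8 to 115.2, 4.84-fold, with a counting interval of 2.19 to 2.36 log2. Of 8 arterial markers 2 were listed and Dll4 was lower, and of 6 venous markers 3 were listed and Selp was higher. The other listed markers of both types did not meet the rule. Dll4 and Selp were already counted in gene lists above, so they are no separate evidence of a shift between these types. Of the listed fibroblast, leukocyte, epithelial and lymphatic markers, 2 reached the minimum mean of 50 and could have met the size rule. They did not: Cd68 (leukocytes) had 102.7 and 123.7, and Flt4 (lymphatic endothelium) 153.3 and 174.2, both named after their values were seen.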

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

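Median-of-ratios scaling, no pseudocount, rules set on reads and matching or correction for GC content were chosen after seeing the data. The drop of Pspc1 held in direction under all 6 alternatives, with log2 ratios from -2.93 without pseudocount to -1.94 with a pseudocount of 5. The counts of higher and lower genes followed the minimum mean and the fold. They were 149 and 306 with no filter on low values, 65 and 113 with a mean of at least 10, 12 and 16 with a mean of at least 100, and 123 and 141 with a fold of at least 1.5. With a mean of at least 50 reads and an interval that excludes 1 they were 206 and 502. These filters admit more or fewer genes by construction. Thinning the control library and an interval beyond 1.5-fold each kept all 20 and 34 genes, and the other scalings and a pseudocount of 5 gave 17 to 23 higher and 24 to 47 lower genes. After subtraction of the median of genes of like length and GC, 22 higher and 29 lower genes met the rule, of which 17 and 26 were also called without it. The lists that stood apart numbered 12 to 18 under 12 alternatives. Under every alternative 7 lists did so: NF-kB, MHC class I, ribosomal and lysosomal genes high, and matrix, splicing and paraspeckle genes low. The Notch, integrin and clock lists had too few members of mean 100 or more for a percentile.

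Scaled by total reads, the log2 ratios of Id1 (-0.093), Mvk (-0.045), Igfbp4 (-0.0026) and Ppia (-0.064) turned negative from values near 0, because that scaling lowers every ratio. For single named genes and lists, 864 other values stayed the same, 334 moved beyond their counting interval, 23 lost and 12 gained their place beyond the threshold. The design's alternative of the point estimate of the fold alone equals the rule as applied, because deposited values carry no interval clause. With 1 library per group no library could be left out. No paired analysis was possible because each group has a single library. Genes of mean 50 or more had 1290 reads or more in each library, and depth sets the width of their counting intervals. The spread between cultures was not measured.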

Other observations

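Several of the largest ratios belonged to genes under the minimum mean of 50, all named here after their values were seen. Some were already counted in lists above and are no separate evidence: Cxcl1 in the NF-kB list, Cebpb in the ATF4 list and Itgb4 in the integrin list. Cxcl2 and Lcn2 also belong to the NF-kB list but lay under its minimum mean of 20. The neutrophil chemokine gene Cxcl1 had 4.46 in the control library and 91.2 in the knockdown library (291 and 4630 reads), and Cxcl2 had 0.70 and 18.1. Lcn2, an iron-binding acute phase protein, had 1.59 and 20.9, and the serine protease inhibitor gene Serpina3g 2.68 and 23.6. The transcription factor gene Cebpb had 12.2 and 35.7, and the interleukin 4 receptor gene Il4ra 14.2 and 51.9. Cebpd, a relative of Cebpb with a mean above 50, met the size rule (26.9 to 89.0). In the other direction the cornified envelope gene Sprr1a had 42.1 and 3.66, the integrin gene Itgb4 53.6 and 8.75, and the receptor kinase gene Kit 57.9 and 13.7.

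Members of the nuclear long noncoding RNA list went both ways, and the list lay at percentile 82.8, or 98.4 with GC matching, and also stood apart with length and GC matched together. Malat1 had 19.3 and 6.38 (counting interval -1.78 to -1.42 log2) and Xist 34.1 and 11.9, both named after their values were seen. Neat1 had 128.6 and 77.8. Snhg8 was higher (62.2 to 141.1), and Gas5, another small nucleolar RNA host gene, had 55.5 and 66.5. Poly-A selection measures only the polyadenylated part of such transcripts.

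For the 3 patterns below, the pooling of lists and the GC-matched tests were chosen after the list percentiles were seen, while length matching had been planned for single lists. Each pooled list had already stood apart in these data, also with random lists matched on length, GC or both. The pooled percentiles were therefore largely set in advance and are no separate evidence. Transcript length here means exonic length, and matching on both used only 5 bins of each property. The biological explanation that the design gives is the loss of Pspc1. In every case it cannot be separated from other differences between 2 single cultures or their libraries. Examples are effects of the hairpin on other transcripts and differences in library preparation, and none of these was tested.

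The NF-kB and MHC class I lists were higher in the knockdown library, and part of that could come from the trend with transcript length or GC content, since class I genes are short. The pooled 26 genes had a median log2 ratio of 0.67, which lay at percentile 100 of random lists matched on mean expression and transcript length and at percentile 100 of those matched on GC content. With both matched together the range was -0.02 to 0.23 (percentile 100), so genes of like length and GC did not in general shift this far. Leukocytes in the culture were not tested as a source, and of 12 leukocyte markers Cd68 (102.7 and 123.7) and Coro1a (6.50 and 9.02) were listed. A response of the endothelial cells to the loss of Pspc1 stays a hypothesis.

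The matrix, integrin, junction, Notch and angiogenesis lists were lower, and they hold many long genes, so transcript length may have contributed. The pooled 74 genes had a median of -0.24, against a range of -0.07 to 0.09 for random lists matched on transcript length and -0.004 to 0.15 for those matched on GC content. The percentile was 0 with either matching and with both together (range -0.08 to 0.09), so genes of like length and GC did not in general shift this far. After the correction for both, Fn1 (log2 ratio -1.01 before, -0.79 after) and Itga6 (-1.08 before, -0.88 after) no longer reached 2-fold. Angpt2 (-1.97), Dll4 (-1.40), Pgf (-1.25), Notch1 (-1.22), Col4a2 (-1.20), Esm1 (-1.19), Notch4 (-1.17) and Cxcl12 (-1.05) still did.

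The splicing factor and paraspeckle lists were lower by small amounts, and transcript length or GC content may have contributed. The pooled 52 genes had a median of -0.26, and random lists centred on 0.003 when matched on transcript length and on -0.02 when matched on GC content. The percentile was 0 in both tests and also with both matched together (range -0.12 to 0.05), so genes of like length and GC did not in general shift this far. After the correction for both, Hnrnpa2b1 went from -1.04 to -0.68 log2 and no longer reached 2-fold. A single library per group leaves open whether a lower level of these transcripts follows the loss of Pspc1.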
